A study of Homo sapiens with 6 samples.

How the data were processed

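Total RNA from MCF7 cells, an established human breast cancer line that expresses the estrogen receptor, was measured on 6 Affymetrix exon arrays. Exon arrays carry small groups of probes, called probesets, most of which lie in single exons, so that one gene is measured by several probesets. Per the labels, 3 arrays were from cells given 0.1% DMSO (control) and 3 from cells given 1 µM camptothecin, all at 6 hours. The deposited table held log2 signals for 287329 probesets, which the authors made with Affymetrix Power Tools and RMA, per the submitters' processing notes. Their versions, the annotation and the genome build were not given in the sources used here. The labels do not say whether the replicates came from separate cultures. The p-values of genes and probesets therefore measure the spread between these samples, which may be technical.

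The deposited log2 values differed in level across arrays. Their medians were 7.76, 7.13 and 7.25 in control replicates 1 to 3 and 7.31, 6.53 and 6.53 in camptothecin replicates 1 to 3. Camptothecin less control came to −0.446, −0.598 and −0.719 for the replicates numbered 1, 2 and 3. Whether this difference was technical or came with the treatment was not tested. Quantile normalization removes it in either case, so a change shared by most genes cannot be seen after it. The design fixed before the data were examined had assumed values already normalized between arrays and used them as deposited. Because the medians differed, the values were quantile-normalized between arrays with limma 3.58.1 in R 4.3.3. That change was made after the array medians, and before any test result, had been seen. The fit on the values as deposited was kept as an alternative, and its counts stand beside the main ones.

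Probesets were named through the platform annotation, which gave 261273 probesets 1 gene symbol, 9155 several and 16901 none. A gene's level was the median of its probesets with 1 symbol, for the 16267 genes with at least 3 of them. Of the annotation's 16941 symbols, 13981 were current, and 16179 matched a current symbol or a single synonym in RefSeq gene records of GRCh38.p14. The array's symbols are printed, with the current one where it differs. Those records also gave gene lengths, used only to place 16160 genes (99.3%) in 4 length classes. The annotation gave no probeset coordinates or strand, so the planned comparison of signal along genes was not made.

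Differences between groups were tested with limma's linear model and moderated statistics, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The replicate number was not in the model. Quantile normalization left the median gene 0.23 higher (log2) in camptothecin, the deposited values put it at −0.32 and median centring at 0.27. Gene differences are therefore given relative to the median gene, while the standard errors and p-values belong to the difference itself. The signal of an exon relative to its gene was the probeset's value minus the gene's level on the same array, tested for 134837 probesets of the 8093 genes whose mean level was at or above 7.08, the median of all probeset values. Gene lists and length classes were tested with camera at a preset correlation between genes of 0.01. Camera sets the statistics of the genes in a list against those of other genes. Its p-values are therefore not a measure of the spread between arrays. The 23 gene lists and 30 genes with known alternative splicing were fixed before the data were examined.

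Genes were named by a rule fixed at the same time: the 12 largest rises and the 12 largest falls among called genes with levels at or above that median, up to 4 called members of each list, and MDM2, EWSR1, YBX1, TOP1 and CDKN1A in any case. All MDM2 probesets were to be given, with up to 10 called probesets in each direction. Genes outside the rule are marked where they appear.

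Control and camptothecin arrays with the same replicate number deviated together. The correlations of their deviations from the group means were 0.594, 0.265 and 0.631, all above 0.1, so the numbers were taken to pair the samples. This came from the data, since the labels give the number only. Values with the replicate number as a block are printed where they change a call or move a count by over 1.5 times. These counts are of the differences themselves, and where centring each array on its median gene moves the share that rose by over 10 percentage points, the centred counts stand beside them. That centring subtracts the median gene level of each array, whereas relative values subtract the median of the gene differences. These shifts are not the same, so the centred counts are not counts relative to the median gene.

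The fits were tested on simulated data with 200 changed genes or probesets and independent noise. For 16267 genes, the fit without the block called 96.4% of changes of 2 (log2) and 14% of changes of 1, and with the block it called 100% and 97.9%. It also called 6 unchanged genes without the block and 19 with it. For 134837 relative probeset signals, the fit without the block called 0% of changes of 1, 52.3% of changes of 2 and 95.8% of changes of 4. With the block it called 1.67% of changes of 1 and 96.2% of changes of 2. Between 4.84% and 5.04% of unchanged items had an unadjusted p under 0.05 in these fits and in that of 287329 probesets. The limma diffSplice test, an alternative for exons, also called 277 unchanged probesets, 263 of them in genes that held no changed probeset. Camera called 10 of 10 shifted lists and 0 of 90 others. These were random lists under independent noise, without correlation between genes. This result therefore does not show how often camera calls real lists whose genes vary together. In 20 further simulations, of the gene fit without the block only, the gene residuals kept the structure the arrays share. The share of unchanged genes with an unadjusted p under 0.05 ran from 0% to 37.5%, with 0 genes called in each. A drawn order that keeps the groups together gives 0% by construction. The fit with the block was simulated only with independent noise and a shift per replicate number, so its calls under shared structure were not tested.

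The alternatives covered the scaling, the replicate block, leaving out each array, the prior of the moderated statistics, signal filters, the gene summary, the minimum difference and other tests of exons and lists. Arrays give no counts, and their number, 3 per group, limits the precision. Levels within a group correlated between 0.9 and 0.955 across probesets. Between groups the lowest was 0.792, for control replicate 1 with camptothecin replicate 3. The highest was 0.944, for control replicate 2 with camptothecin replicate 1, so the ranges overlapped. No column of sample values was left unmapped.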

Results

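The data were exon-level RNA signals from MCF7 cells treated for 6 hours with 1 µM camptothecin or with 0.1% DMSO as control, with 3 arrays in each group. Camptothecin traps topoisomerase I, an enzyme that relaxes DNA during transcription and replication, on the DNA. The title of the series concerns exon skipping under genotoxic stress, and the comparison of camptothecin with control asks how gene levels and exon signals differed after treatment. All gene values are log2 differences relative to the median gene, ± SE from limma (n = 3 per group).

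Among called genes at or above the median level, the largest rises were led by genes that p53 induces after DNA damage. BTG2, an antiproliferative gene, rose by 2.18 ± 0.25 (limma adjusted p = 0.0109), which is 4.54-fold, and GDF15, a secreted stress factor, by 2.16 ± 0.24 (adjusted p = 0.0109). PLK3, a stress-responsive kinase, rose by 2.06 ± 0.24, GADD45A, which acts in growth arrest, by 1.93 ± 0.21, and CDKN1A, the cyclin-dependent kinase inhibitor p21, by 1.66 ± 0.22 (adjusted p = 0.016). TP53INP1 rose by 1.58 ± 0.34, SERTAD1 by 1.57 ± 0.24 and PHLDA3 by 1.27 ± 0.27. The transcription factor genes FOS, FOSL1 and DDIT3 rose by 1.34 ± 0.29, 1.32 ± 0.31 and 1.18 ± 0.29, and the zinc finger gene ZNF425 by 1.24 ± 0.28.

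Among genes at or above the median level, the largest falls were steeper than the largest rises. DDX58 (now RIGI), a sensor of viral RNA, was 10.8-fold lower (−3.43 ± 0.58, limma adjusted p = 0.0386). C2orf12 (a synonym of RBMS1) was at −3.23 ± 0.28 (adjusted p = 0.0109). That value is of the 4 probesets under this symbol and need not hold for RBMS1 as a whole. SRGAP1, a regulator of Rho-type GTPases, was at −2.88 ± 0.26. The transcription factor genes ELF1, GRHL2 and ZNF148 fell, with differences of −2.70 ± 0.36, −2.35 ± 0.29 and −2.28 ± 0.42. NRIP1, a corepressor of nuclear receptors, was at −2.67 ± 0.29, and MLL3 (now KMT2C), a histone methyltransferase gene, at −2.37 ± 0.28. PPP1R12A, ERBB2IP (now ERBIN), PIK3R1 and ATF7IP fell, with differences of −2.60 ± 0.43, −2.44 ± 0.41, −2.41 ± 0.40 and −2.30 ± 0.43. These values are medians over the probesets of a gene, and some probesets did not fall. By quantile-normalized signal, DDX58 probeset 3203122 went from 5.9 in control to 6.93 in camptothecin. SRGAP1 probeset 3419719 went from 6.32 to 6.45 and GRHL2 probeset 3109695 from 7.93 to 8.25. The falls need not hold for every exon of these genes. All 24 genes kept their sign relative to the median gene on the values as deposited, from which median centring gives the same relative differences by construction.

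**Figure D1:**
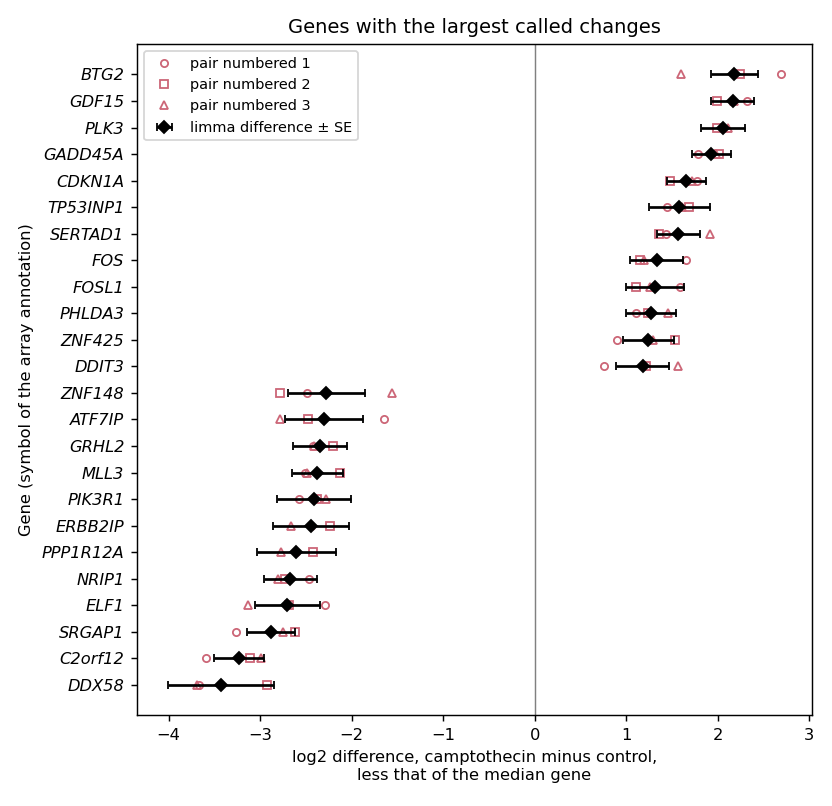
Log2 difference between camptothecin and control, less that of the median gene, for the 12 largest rises and 12 largest falls among called genes with levels at or above the median of all probeset values; black diamonds are limma differences with SE and open symbols the differences within the 3 pairs of arrays with the same number. Rises run from 1.18 (DDIT3) to 2.18 (BTG2) and falls from −2.28 (ZNF148) to −3.43 (DDX58).

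In all, limma called 310 of 16267 genes, of which 54 rose and 256 fell, and 1155 of 287329 probesets, of which 96 rose and 1059 fell. With the replicate block 5954 genes (3724 rose and 2230 fell) and 22409 probesets (4110 rose and 18299 fell) were called, and the 310 genes were all among them with the same sign. With the block and each array centred on its median gene level, a choice made after seeing the data, 1977 genes rose and 2427 fell. That level is not the shift taken off the printed differences. On the values as deposited, a combination also chosen after seeing the data, the block gave 76 genes that rose and 5185 that fell. The numbers of rises and falls with the block therefore depend on the scaling. Without the block, the values as deposited gave 0 called genes, with 2467 at an unadjusted p under 0.05, and 0 called probesets, with 44555 at an unadjusted p under 0.05. Median centring gave 9 called genes (5 rose and 4 fell), and leaving out control replicate 2 or camptothecin replicate 2 gave 0.

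Among gene lists, p53 targets rose as a list: 9 of 39 measured members rose, none fell and 30 did not pass, with a median of 0.67 (limma camera adjusted p = 2.39e-12). Besides the members above, TP53I3 and TNFRSF10C, outside the naming rule, were called. With the replicate block 31 rose and 1 fell, and adjusted over the list alone 28 rose. MDM2, which encodes the ubiquitin ligase of p53, was at −0.21 ± 0.27 (adjusted p = 0.965). That gene value is a median of 23 probesets. By their own signal 1 of these probesets rose without the block, and 4 rose and 0 fell with it. Of 30 immediate early and stress-induced genes 4 rose, including EGR1 (1.08 ± 0.26) and IER5 (0.98 ± 0.24), and the list median was 0.37 (adjusted p = 1.51e-05). With the block 19 rose, and adjusted over the list alone 8 rose. With an estimated correlation neither list was called (adjusted p = 0.168 and adjusted p = 0.295).

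Genes of G2 and mitosis fell as a list, with a median of −1.16 over 29 measured members (camera adjusted p = 3.99e-14). The 8 called members included the mitotic motor genes KIF11 (−2.67 ± 0.42) and CENPE (−2.32 ± 0.42), the checkpoint kinase gene TTK (−2.46 ± 0.46) and HMMR (−2.23 ± 0.42). The level of KIF11 and of CENPE was at or below the median olfactory receptor gene on 1 camptothecin array each. The mean of CENPE in camptothecin, 4.34, was below the olfactory receptor mean of 4.56. The sizes of the falls of KIF11 and CENPE are therefore uncertain. With the block 22 fell, and adjusted over the list alone 17 fell. Genes of DNA damage signalling and repair had a median of −0.63 over 39 members (adjusted p = 8.09e-08). BRCA2, which acts in homologous recombination, fell (−2.00 ± 0.33), as did the helicase gene WRN (−1.57 ± 0.26), and 37 members did not pass. With the block 18 fell and 1 rose, and adjusted over the list alone 7 fell. With an estimated correlation neither list was called (adjusted p = 0.418 and adjusted p = 0.461).

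Of 36 replication-dependent histone genes 10 were measured, with a median of −0.96 (camera adjusted p = 0.00119), and HIST1H1D (now H1-3), a linker histone gene, fell (−1.99 ± 0.28). With the block 5 fell and 1 rose, and adjusted over the list alone 5 fell and 1 rose. SR proteins, hnRNPs and splicing kinases had a median of −0.36 over 38 members (adjusted p = 0.00198). The kinase genes DYRK1A (−2.11 ± 0.36) and SRPK2 (−1.98 ± 0.29) fell and 36 members did not pass, while with the block 8 fell and 4 rose, or 9 fell and 1 rose with each array centred on its median gene. Adjusted over the list alone 2 fell. Neither list was called with an estimated correlation (adjusted p = 0.58 for each).

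Estrogen-responsive genes had a median of −0.33 over 23 members (camera adjusted p = 0.00508). NRIP1 fell and 22 did not pass, against 6 that fell and 1 that rose with the block (7 and 0 with each array centred on its median gene) and 4 that fell adjusted over the list alone. The 13 heat shock protein genes had a median of −0.27 (adjusted p = 0.0339) with 0 called members, and 3 fell with the block. That call was lost on the values as deposited (adjusted p = 0.0803) and with median centring (adjusted p = 0.0846). With an estimated correlation these lists were not called (adjusted p = 0.418 and adjusted p = 0.58). Of 30 very long genes 3 fell, the phosphatase gene PTPRK (−1.64 ± 0.29), NBEA (−1.51 ± 0.27) and SUPT3H (−1.36 ± 0.24), and the median was −0.76 (adjusted p = 6.24e-10). In camptothecin SUPT3H was at or below the median olfactory receptor gene on 3 arrays and NBEA on 1, so the sizes of these falls are uncertain. Adjusted over the list alone 11 fell, with the block 16 fell, and the adjusted p was 0.168 with an estimated correlation.

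The other 14 lists were not called by camera in the main setting. The rotation test fry, which does not compare a list with other genes, called 1 of them, snoRNA host genes (adjusted p = 0.00267). Genes of G1/S and replication had a median of −0.26 (camera adjusted p = 0.0664) and were called as deposited (adjusted p = 0.00929), with median centring (adjusted p = 0.00881) and with the block (adjusted p = 0.0474, or adjusted p = 0.49 with the block and an estimated correlation). Topoisomerases were at −0.58 (adjusted p = 0.0863, or 0.0443 with median centring), and TOP1, the target of camptothecin, was at −0.68 ± 0.24 (adjusted p = 0.322). In the unfolded protein and integrated stress response list, with a median of −0.07 and a mean of 0.08, DDIT3 and CHAC1 (0.95 ± 0.22) rose. Medians were −0.14 for core spliceosome genes, −0.30 for the FET family and YB-1, −0.17 for luminal epithelial markers and 0.16 for snoRNA host genes. They were 0.04 for NF-kB targets and −0.02 for oxidative phosphorylation genes, whose mean was 0.11. BCL2 family genes were at 0.03 and at −0.05 on deposited values, and cytosolic ribosomal protein genes at −0.02 and at 0.10 on deposited values (adjusted p = 0.398, or 0.00896 with median centring). Markers of other cell types had medians of 0.27 for leukocytes (adjusted p = 0.0519), 0.22 for fibroblasts (adjusted p = 0.135) and −0.05 for basal epithelium (adjusted p = 0.816). The leukocyte markers were called as deposited (adjusted p = 0.00593) and with median centring (adjusted p = 0.0207), and the fibroblast markers with median centring (adjusted p = 0.0443). With an estimated correlation, run on the quantile-normalized values only, the adjusted p was 0.58 for leukocyte markers, 0.7 for fibroblast markers, 0.58 for G1/S genes, 0.419 for topoisomerases and 0.817 for ribosomal protein genes.

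Of these 14 lists only the unfolded protein list had called members without the block, the 2 named. With the block 4 of its members rose and 4 fell, and 2 topoisomerase genes and 0 members of the FET list fell. Among G1/S genes 4 rose and 8 fell, or 2 and 9 with each array centred on its median gene, among core spliceosome genes 4 rose and 5 fell (2 and 6 centred), and among luminal markers 3 rose and 2 fell (0 and 3 centred). Of NF-kB targets 6 rose and 2 fell and of basal markers 3 rose and 1 fell. In the BCL2, fibroblast, leukocyte and oxidative phosphorylation lists 5, 5, 4 and 3 rose (3, 1, 2 and 1 centred) and none fell. Of ribosomal protein and snoRNA host genes 1 each rose, and 0 when centred.

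**Figure D2:**
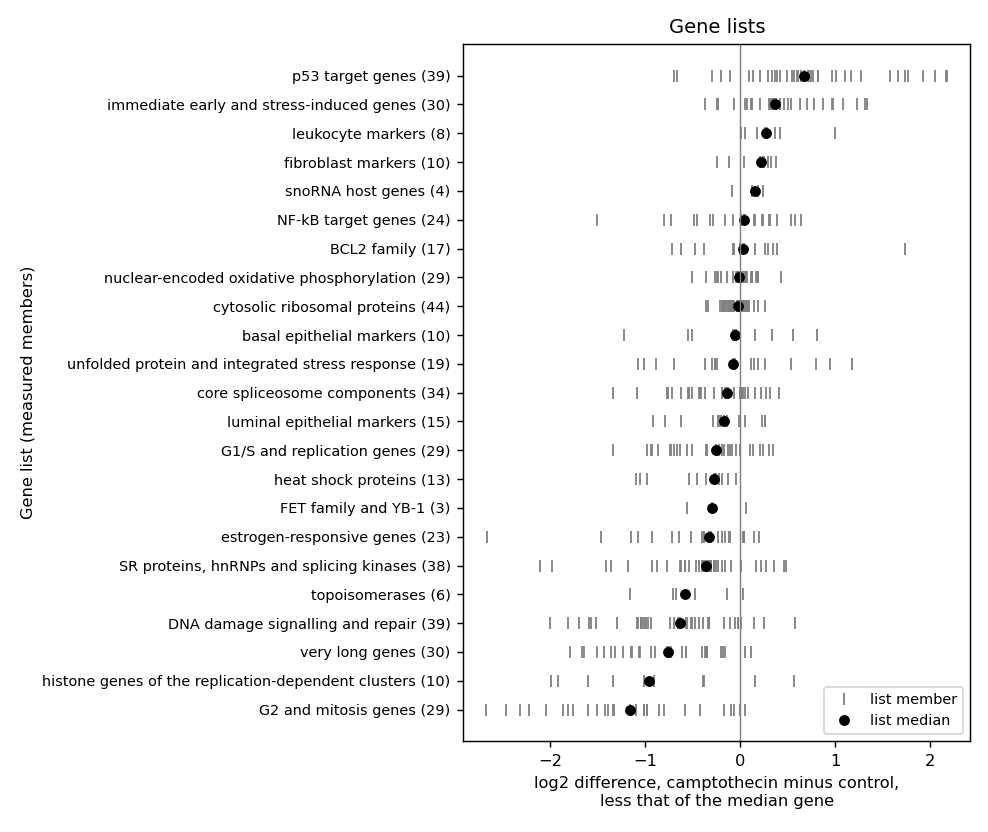
Log2 difference between camptothecin and control, less that of the median gene, for the members (ticks) and medians (dots) of 23 gene lists, with measured members in parentheses. Medians run from −1.16 for G2 and mitosis genes to 0.67 for p53 target genes.

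Long genes were lower than short genes. Median differences were 0.17 for 3984 genes under 10 kb, 0.08 for 4560 genes of 10 to 30 kb, −0.18 for 4704 genes of 30 to 100 kb and −0.36 for 2912 genes of 100 kb and over. The longest class held 194 of the called falls and 1 rise, and the shortest 7 falls and 25 rises. Among the 12 largest falls, SRGAP1, ELF1, NRIP1, PPP1R12A, ERBB2IP, MLL3, GRHL2, ATF7IP and ZNF148 were in the longest class. DDX58 and PIK3R1 were of 30 to 100 kb, and C2orf12 had no class. The splicing kinase genes DYRK1A and SRPK2 were in the longest class too. With the block 1011 of the longest genes (34.7%) and 56 of the shortest (1.41%) fell, while 271 (9.31%) and 1505 (37.8%) rose. With the block and each array centred on its median gene 1069 of the longest and 66 of the shortest fell, while 124 (4.26%) and 864 (21.7%) rose. The longest class less the shortest came to −0.53, or −0.94 among genes at or above the median level, and to −0.64, −0.48 and −0.54 within the pairs numbered 1, 2 and 3. The camera adjusted p for the longest class was 2.9e-18, and with an estimated correlation the adjusted p was 0.00289, or 0.0295 with the block too. With an estimated correlation and no block, genes under 10 kb and of 10 to 30 kb were not called (adjusted p = 0.122 and adjusted p = 0.0667). An exact two-sided permutation test of the long minus short values of the 6 arrays gave p = 0.1, the smallest that 3 arrays against 3 allow. The 204 olfactory receptor genes, which this cell type is not expected to express and which were looked up after seeing the data, had a median of 0.07 relative to the median gene, and 0.12, 0.05 and 0.17 within the pairs. Their median level on the arrays, not set against the median gene, was 0.33 higher in camptothecin, and higher by 0.35, 0.26 and 0.37 within the pairs. An exact two-sided permutation test that ignores the pairs gave p = 0.4, and one over the signs of the 3 pairs gave p = 0.25, the smallest it allows.

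**Figure D3:**
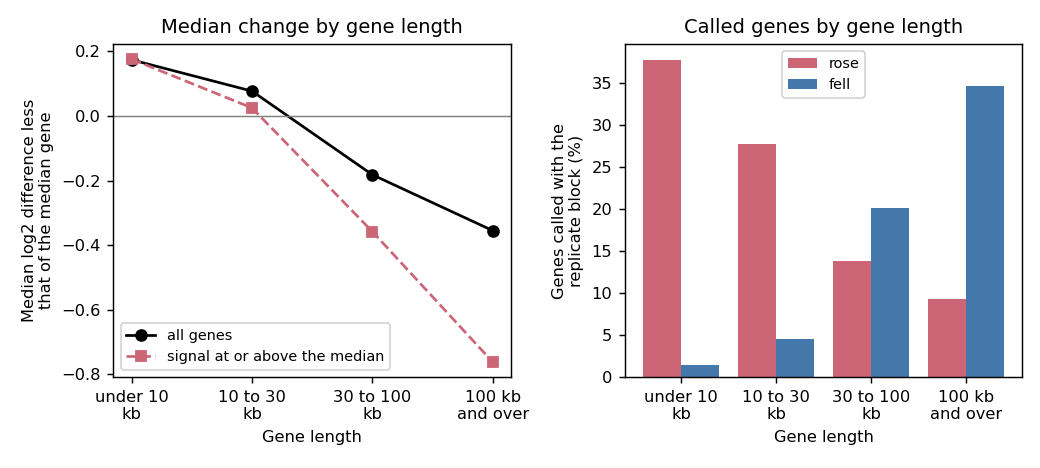
Left, median log2 difference less that of the median gene by gene length class, for all genes and for genes with levels at or above the median; right, percent of the genes of each class that were called with the replicate block and rose or fell, with arrays not centred on the median gene. The median over all genes runs from 0.17 under 10 kb to −0.36 at 100 kb and over, and the share that fell from 1.41% to 34.7%.

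For exon signals relative to their genes, limma called 0 of 134837 probesets, with or without the replicate block, and the lowest adjusted p was 0.391, or 0.0751 with the block. In simulated data these fits called 0% of changes of 1 (log2) without the block and 1.67% with it. Exon changes of that size would therefore mostly be missed. At an unadjusted p under 0.05 there were 9329 probesets (6.92%), 4931 higher and 4398 lower, and 22682 (16.8%) with the block. The limma diffSplice test called 432 probesets in 305 genes, 212 higher and 220 lower, and 9043 with the block. In simulated data that test also called 277 unchanged probesets, and another split of the 6 arrays gave it 1580.

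In the list of 30 genes with known alternative splicing, 23 were tested with 451 probesets, and 0 were called by limma over all probesets. Adjusted over the list alone 1 was called, an MDM2 probeset, and 11 in 7 genes with the block. The diffSplice test called 2, both in MDM2, and with the block 48 in 18 genes. EWSR1 and YBX1, RNA-binding protein genes, were at −0.30 ± 0.25 (adjusted p = 0.867) and 0.06 ± 0.21 (adjusted p = 0.417) as genes, and none of their probesets was called by limma over all probesets or adjusted over the list alone. The diffSplice test with the block called 1 EWSR1 probeset, which was higher, and 0 of YBX1. As a gene EWSR1 was called with the block on the values as deposited (adjusted p = 0.0154), not set against the median gene, and not with the block on the quantile-normalized values (adjusted p = 0.685).

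MDM2 had 23 probesets, with 2 that stood apart. In order of identifier, which is no measured position, all probesets from 3421307 to 3421316 were higher relative to the gene. Those from 3421322 on ran from −0.55 to 0.14. Probeset 3421312 went from 6.81 ± 0.44 in control to 9.83 ± 0.57 in camptothecin (SD, n = 3), which was 3.00 ± 0.28 higher relative to the gene (SE). Its p ranked 1 of all probesets tested, with an adjusted p of 0.391 by limma and 0.00638 adjusted over the list alone. Probeset 3421313 went from 4.56 ± 1.29 to 8.17 ± 0.80 (SD), 3.59 ± 0.61 higher relative to the gene (SE, adjusted p = 0.391 by limma and 5.95e-05 by diffSplice). It was at or below the median olfactory receptor gene on 2 of 3 control arrays, so the size of its difference is uncertain. The same held for 3421310 on 1 control array and for 3421341 on 2 control and 3 camptothecin arrays. The other 21 probesets had relative differences from −0.63 (3421305) to 1.80 (3421310). Among them 3421307, 3421315, 3421311, 3421316 and 3421304 were at 1.00, 0.82, 0.76, 0.76 and 0.50. Probesets 3421335, 3421339, 3421329, 3421303, 3421336, 3421337, 3421328, 3421340, 3421338, 3421325, 3421323 and 3421322 lay between 0.14 and −0.27. Probesets 3421334 and 3421341 were at −0.37 and −0.55.

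**Figure D4:**
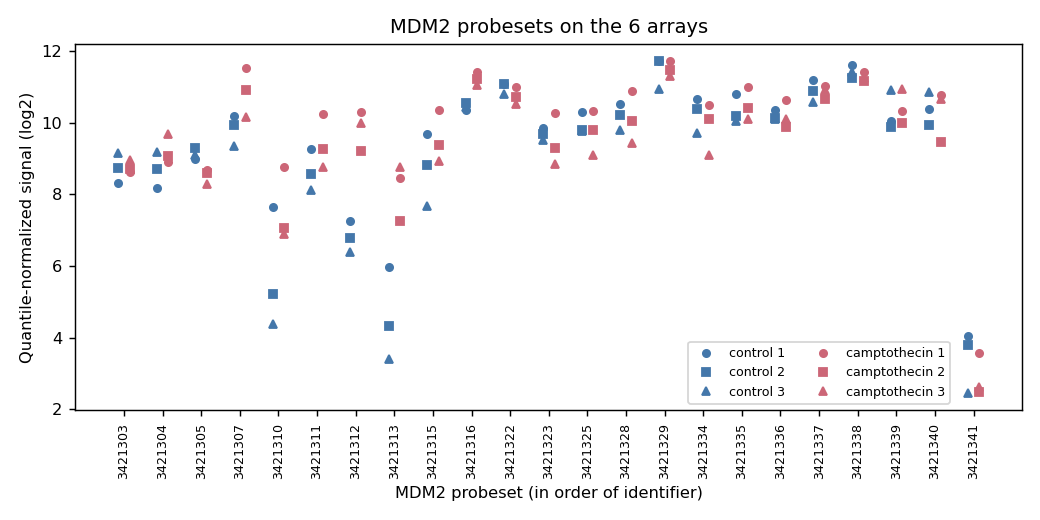
Quantile-normalized log2 signal of the 23 MDM2 probesets on the 6 arrays, in order of probeset identifier, which is no measured position; symbols give the replicate number and colours the group. Probesets 3421312 and 3421313 rise from means of 6.81 and 4.56 in control to 9.83 and 8.17 in camptothecin.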

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

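The alternatives that combine the replicate block with another scaling, centre arrays on the median gene, leave out a pair, set levels against olfactory receptor genes or pair diffSplice or an estimated correlation with the block were chosen after seeing the data. The 43 named genes kept their direction in every alternative run for them, with 247 results that lost and 3 that gained a call. The length result kept its direction under its 15 alternatives, and the longest class, the only one whose call was followed, kept its call. Called probesets, 1155, became 0 on the values as deposited, 0 with median centring, 3377 with an intensity trend and robust prior and 2985 at signals at or above the median, and ran from 0 to 0 with each array left out. Called genes, 310, became 0 as deposited, 9 with median centring, 186 with the signal filter and 522 with the mean over probesets, and ran from 0 to 642 with each array left out: 27, 0 and 642 without control replicates 1, 2 and 3, and 80, 0 and 19 without camptothecin replicates 1, 2 and 3. Called lists, 9, became 0 with an estimated correlation and 4 with fry (p53 targets, immediate early, snoRNA host and very long genes). Called exon signals, 0, became 432 with diffSplice, and those of the splicing list, 0, became 2.

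With the replicate block, 22409 probesets and 5954 genes were called. On the values as deposited the block gave 71923 probesets (1017 rose and 70906 fell), 5261 genes (76 rose and 5185 fell) and 14 lists. With median centring it gave 23130 probesets, 4239 genes and 14 lists, and centred on the median gene 4404 genes. Leaving out both arrays numbered 1, 2 or 3 gave 2053, 4021 and 2409 genes. The block with diffSplice gave 9043 exon signals and 48 in the splicing list, and with an estimated correlation 0 lists. Of the lists, the block changed only the call of G1/S and replication genes. The causes of these changes were not tested. The comparison of signal along genes and its alternatives were not run, for want of probeset coordinates. The values carry no signal over background. Of 98 genes and MDM2 probesets set against the median olfactory receptor gene, 9 were at or below it on at least 1 array.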

Other observations

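The tests of the interferon-stimulated genes for a replicate number batch and for control replicate 1, those of long genes for signal level, replicate number batch and gradient, the split test of gene length and the length tests of histone and heat shock genes were chosen only after a result that bears on them was seen. The list of interferon-stimulated genes was itself written after DDX58 had been seen among the largest falls.

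Interferon-stimulated genes, which cells switch on in response to interferon or viral RNA, were lower in camptothecin, with a median of −1.10 relative to the median gene over 33 measured genes. IFIT3 was at −2.94 ± 0.96 (limma adjusted p = 0.201, or 0.00205 with the replicate block), IFI44 at −2.81 ± 0.95 (0.212, or 0.00201), IFI44L at −2.26 ± 0.73 and RSAD2 at −2.11 ± 0.62. IFI44 was at or below the median olfactory receptor gene on 2 camptothecin arrays, so its size is uncertain. Without the block only DDX58 of the 33 was called, and with it 23 fell and 0 rose. The camera p was 2.16e-11, and p = 0.207 with an estimated correlation. The arrays differed within groups too: the median deviation of these genes from their means was 1.35 in control replicate 1 and −0.43 in control replicate 2.

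In the pairs numbered 1, 2 and 3, 31, 26 and 32 of the 33 interferon-stimulated genes were lower, and a batch shared by a pair cancels in these counts by design, so the lowest, 26, does not test it. Relative to the median gene the list median was −1.213, −0.616 and −1.451 in these pairs, and −1.036 without the pair numbered 1. That argues against a high level in control replicate 1 alone. The deviation in control replicate 3 was also high, at 0.622, and the pair of control replicate 2 fell least. Levels that vary among the controls therefore stay open. Less genes of the same length and signal the median was −1.035, below all 10000 matched random lists, which argues against gene length. Treatment, the difference the design names, and differences between cultures, which the labels do not describe, stay open and were not tested apart.

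The fall of long genes was set against signal level, replicate structure and transcript length. The long minus short difference was −0.938 among genes at or above the median level, which argues against low signal as its source. Long and short genes were not matched on signal there, so signal level is not excluded in full. Between 109 long and 754 short genes of that level with 8 to 12 probesets the difference was −0.669. This argues against transcript length, as the number of probesets shows it, as the whole account, and leaves a part open. The pair closest to 0 was at −0.475, which likewise does not test a batch shared by a pair. Regression on the difference between the other 2 replicate numbers took the pairs, at or above the median level, from −1.002, −0.781 and −1.014 to −0.793, −0.581 and −0.91, so a gradient between replicates took up part of the difference; a first version with replicate 1 less replicate 3 for every pair, contrary to its plan, gave −0.719, −0.581 and −0.741. Treatment, the difference the design names, stays open without a test of how it would act, as does RNA degradation, for want of probeset positions.

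Gene length was also tested as the explanation of each called list, by setting its members against 10000 random lists matched on length and signal. The p53 targets (0.679), immediate early genes (0.242), G2 and mitosis genes (−1.067), DNA damage genes (−0.318), SR proteins, hnRNPs and kinases (−0.35) and histone genes (−1.141) lay outside the middle 95% of matched lists in each pair, which argues against gene length as the whole account. Estrogen-responsive genes (0.001) and very long genes (−0.239) lay inside it, so the shifts of these lists may be those of long genes. Heat shock genes (−0.371) lay outside it in 2 pairs and inside in the pair numbered 2, which leaves length open. These ranks treat genes as independent, and the lists lost their calls with an estimated correlation.

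Probesets of one gene spread further apart in long genes. The median within-gene SD of the probeset differences was 0.65, 0.56 and 0.68 at 100 kb and over and 0.36, 0.35 and 0.35 under 10 kb in the pairs numbered 1, 2 and 3, a ratio of 1.81, 1.60 and 1.93. Between replicates of one group the SD was as large in long genes, from 0.532 to 0.763, and larger in short genes, from 0.407 to 0.604, so the ratio there, from 1.177 to 1.501, was lower.

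With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1155 probesets and 310 genes, against at most 0 in the others, which was 1 of 10 for each. Exon signals were 0 in all 10. The diffSplice test gave 432, against 1580 in the split that sets control replicates 1 and 2 with camptothecin replicate 1 apart from the rest, and 2 of 10 splits gave as many. Those arrays are the ones above 0 on the first principal component (55.3% of the variance), which points to a structure of the samples. Camptothecin was also lower than control on that component in each pair (0.678 and 0.027, 0.249 and −0.218, −0.087 and −0.65). For gene lists 5 of 10 splits gave at least the 9 of the real one, with up to 11, which also points to structure that the arrays share. The long minus short difference was 0.529 in size, against at most 0.41, which was 1 of 10. With the block, 4 splits part all 3 pairs, and the real one gave 5954 genes against at most 0, which was 1 of 4. The other splits each set arrays of both groups on one side.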
